A study of Equus caballus with 20 samples.

How the data were processed

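Blood RNA of 10 Arabian horses was measured by RNA sequencing in 20 libraries, 10 labelled as taken before and 10 as taken after an endurance run. Per the labels' protocols, libraries were made from total RNA with a TruSeq RNA kit, and the series' design text gives single-end reads of 75 cycles. The labels' protocols and the design text name different RNA isolation kits. This TruSeq chemistry does not mark the strand, so reads of overlapping antisense genes cannot be told apart.

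The authors deposited 1 file of whole-number read counts per gene for each library, without normalization or pooling. FastQC, STAR, RSEM, HTSeq and DESeq2 and the horse genome build EquCab3.0 are named in the submitters' processing notes, without roles or versions. The deposited counts end in the 5 summary lines that HTSeq writes. The annotation release, strand setting and read filters are not given in the sources used here. HTSeq's lines for reads outside genes, ambiguous between genes, not aligned or aligned to several places held 15.9% to 22.8%, 0.675% to 1.42%, 31.1% to 35.4% and 2.52% to 6.07% of all reads. They were left out of library sizes and tests. Reads counted to genes were 39.1% to 45.8% of all reads.

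Genes carry Ensembl identifiers only, and no annotation was used here. Gene names, positions and functions are therefore not given. The 32 gene lists fixed before the data were examined (fat and sugar metabolism, insulin signalling, blood cell types, stress and immune responses) could not be matched to identifiers, and neither could haemoglobin or mitochondrial genes. The gene list tests, list scores, removal of haemoglobin genes and shares of haemoglobin and mitochondrial reads were not run.

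Genes were filtered with edgeR's filterByExpr on the run label, which kept 12914 of 30371 genes, and libraries were scaled by TMM. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with run as the tested term and the horse label as a block, over all 20 libraries. The block was part of the design because the labels give a subject for each library and the design text states that each horse was sampled before and after the run. P-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. Standard errors were taken as the log2 fold change divided by the square root of F. CPM values of the genes named for the run comparison use the TMM-scaled library size, and CPM values of the genes present or near 0 use the total gene count. Log2 CPM for principal components used a prior count of 2. The rule for named genes asked for a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 1 and the same direction in all 10 horses, plus members of the fixed lists. With no gene passing and no symbols, the 2 identifiers with the smallest p in each direction are given instead.

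Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, a filter of 1 CPM in 10 libraries, no horse block, and each horse left out in turn. Added afterwards were total count or share of reads outside genes as a covariate beside the horse block, and the first 2 principal components as covariates in a fit without the block. Library measures were compared with an exact sign-flip test over 1024 sign patterns, and with 100000 permutations without the horse label. Other splits of the libraries were drawn 50 times for each of 2 models, the real split included.

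The pairing of libraries by horse label was checked from correlations of deviations from the run-label means, with 100000 permutations of the horse labels added afterwards. Libraries were then matched from the data, with settings chosen after the data were seen. The genes present or near 0 were looked at first, then 4 wider definitions of them, then 8 panels, of which the one described here was kept; all of these and further panels are reported. The panel used log2(CPM + 0.5), genes with a mean above 0, removal of the first 2 components and genes that kept over 0.8 of their SD. The 100 most variable were taken, and the matching with the highest total correlation was found with networkx 3.6.1. Genes present or near 0 were those with at most 3 reads in at least 2 libraries and at least 1 CPM in at least 2, with at most 1 library between these limits and a gap above 2.5 on the log2 scale. Wider definitions asked for a gap of at least 1.5, 2, 2.5 or 3 on the log2 scale, wider than the range of the libraries above it. They also asked for at least 2 libraries on each side of the gap and a highest value of about 0.5 CPM or more. The matching names libraries that resemble each other and was not used to assign a run or horse to any library. No edgeR, DESeq2 or limma-voom fit used the matching. Its pairs entered permutation tests of the genes present or near 0 and of ENSECAG00000043002, and counts on the first component.

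The tests were tested on simulated data. In counts drawn for the 12914 real genes with 200 of them changed, the edgeR test recovered 48 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 5 false calls. The changed genes had a mean of at least 2 CPM and the same change in all horses. In simulated counts of 30371 genes with differences between animals in 300 of them, the matching recovered 10 of 10 true pairs, and with no such differences 0 of 10. The size of these differences was set and not taken from the data. Apart from a shared axis, no other grouping of the libraries was simulated. The simulation therefore cannot tell animals from other shared structure in the real libraries. Depth was 17280700 to 29717700 gene counts per library. Reads carry no molecular identifiers, so counting error is a lower bound on the error.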

Results

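Whole-blood RNA of Arabian horses was sequenced in 20 libraries, labelled as coming from 10 horses that were each sampled before and after an endurance run. The design text gives the number of samples sequenced as 10 in one place, while 20 libraries with different counts are labelled, and n = 10 per run label rests on the labels. The design therefore has 1 comparison, after against before the run within the horse, with 10 libraries under each run label. Its stated interest is how lipid and carbohydrate metabolism change in blood under endurance exercise. The measurements are read counts for 30371 horse genes, given by Ensembl gene identifier alone. The files do not pair the identifiers with gene names, so genes are given by identifier and no pathway or cell type is described. The horse and run of a library are those of its label throughout, and "before 1" stands for the library labelled as taken from horse 1 before the run.

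The libraries labelled as taken before the run held 20740800 ± 2438800 gene counts (mean ± SD, n = 10) and those labelled after held 24680000 ± 3257670 (n = 10). Single libraries ranged from 17280700 to 29717700. The after library was the deeper in 9 of the 10 horses, by 3939280 counts on average. An exact two-sided sign-flip test over the 10 horses gave p = 0.0156, and 0.0625 after Benjamini-Hochberg adjustment over 8 library measures. A two-sided permutation test that ignores the horse label, added after the data were seen, gave an adjusted p of 0.0294 for depth. Among the 8 measures, depth, the share of the 10 most abundant genes and the number of genes with a read were planned. The others, shares of all reads, were not planned. No adjustment over the planned measures alone was made. Reads that aligned outside annotated genes made up 20.4% ± 1.57 of all reads before and 17.9% ± 1.31 after. This share was lower after the run in 9 of 10 horses (adjusted p = 0.0625, exact sign-flip test; 0.0112, permutation test without the horse label). The number of genes with at least 1 read was 16728 ± 553 before and 16714 ± 512 after (adjusted p = 0.949, exact sign-flip test). The 10 most abundant genes took 6.06% ± 0.839 of the gene counts before and 6.72% ± 1.22 after (adjusted p = 0.307, exact sign-flip test). The highest share was 9.47%, in the library after 8, and without horse 8 the mean difference was 0.296 percentage points in place of 0.662.

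**Figure D1:**
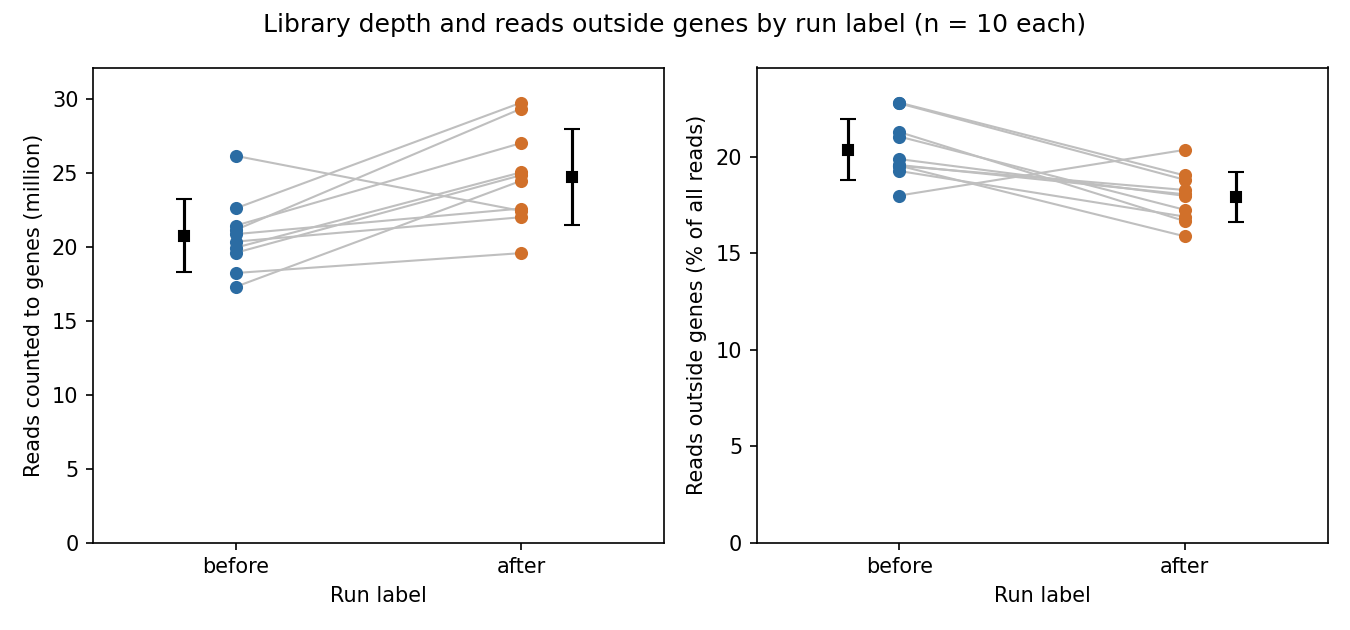
Reads counted to genes (left), and reads outside genes, in percent of all reads (right), for each library by run label. Points are libraries, grey lines join libraries with the same horse label, and black squares with bars are the mean and SD of 10 libraries. The means are 20740800 and 24680000 on the left, and 20.4% and 17.9% on the right.

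With edgeR, no gene passed the test between the libraries labelled before and after the run. Of 12914 genes tested with edgeR's quasi-likelihood test and the horse as a block, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.923. At an unadjusted p under 0.05 there were 391 genes, 240 higher and 151 lower after the run, where 646 are expected by chance. With single horses left out this count ranged from 177 (without horse 6) to 1537 (without horse 7), and it was also above 646 without horse 10 (1021). The majority direction turned with total count as a covariate (63 higher, 154 lower), with the share of reads outside genes as a covariate (384 and 457), and without horse 5 (95 and 104) or horse 10 (494 and 527). The same count of 0 was obtained with limma-voom, and with edgeR without the horse block. DESeq2 called 1 gene, ENSECAG00000043002, with an adjusted p of 0.000111 (log2 fold change 2.87). Only 11 genes moved the same way in all 10 horses, where 25.2 would be expected if the genes and horses moved at random. No gene met the rule for named genes, which required an adjusted p under 0.05.

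The precision of the estimates is given for the difference between the run labels. It describes the effect of the run only if the labels follow the animals. The 95% interval of the log2 fold change had a median half-width of 0.51, and 92.3% of the genes had a half-width under 1, that is, under a 2-fold change. Such an interval can still reach past a 2-fold change, since the half-width is added to the estimate. When a 4-fold change was added to 100 genes of the deposited counts, 89 were recovered at an adjusted p under 0.05, and of 100 genes changed 2-fold, 51 were recovered, with 0 false calls. The changed genes were drawn from those with a mean of at least 2 CPM, and the added change was the same in all horses. Recovery of genes with lower counts, or of a response that differs between horses, was not tested.

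The genes with the smallest p in each direction, among those with a mean log2 CPM of at least 1, are given as values. They were chosen after their values were seen, and none passed the test (edgeR adjusted p = 0.923 for each). ENSECAG00000043002 had 2.56 ± 1.83 CPM before the run and 33.1 ± 36.5 CPM after (mean ± SD, n = 10 each). Its log2 fold change was 2.91 with a standard error of 0.67, and 8 of 10 horses had the higher value after. The log2 fold change was 3.68 without the horse block and 2.32 with total count as a covariate. ENSECAG00000017024 had 29.6 ± 4.54 CPM before and 41.4 ± 8.73 CPM after, a log2 fold change of 0.47 with a standard error of 0.12. It was higher after the run in 10 of 10 horses. ENSECAG00000012086 had 19.7 ± 4.33 CPM before and 12.8 ± 4.58 CPM after, a log2 fold change of -0.68 with a standard error of 0.16, and was lower after in 10 of 10 horses. ENSECAG00000031565 had 9.81 ± 4.04 CPM before and 5.45 ± 1.22 CPM after. Its log2 fold change was -0.78 with a standard error of 0.21, and 8 of 10 horses had the lower value after. With total count as a covariate, its log2 fold change was -0.31, and with the share of reads outside genes, -0.43.

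The libraries nevertheless differed widely from one another. The first principal component of log2 CPM held 50.1% of the variance and the second 18.1%. The run label accounted for 1.69% of the first component and 8.34% of the second. The horse label accounted for 52.4% and 45.4%, where 47.4% is expected of 10 arbitrary pairs. Of the 10 libraries with the highest scores on the first component, 5 were labelled before and 5 after the run. The libraries before 3, before 4 and after 4 lay at 87.3, 69.7 and 66.1, and after 5, after 10 and before 7 lay at -65.9, -65.7 and -64.1.

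**Figure D2:**
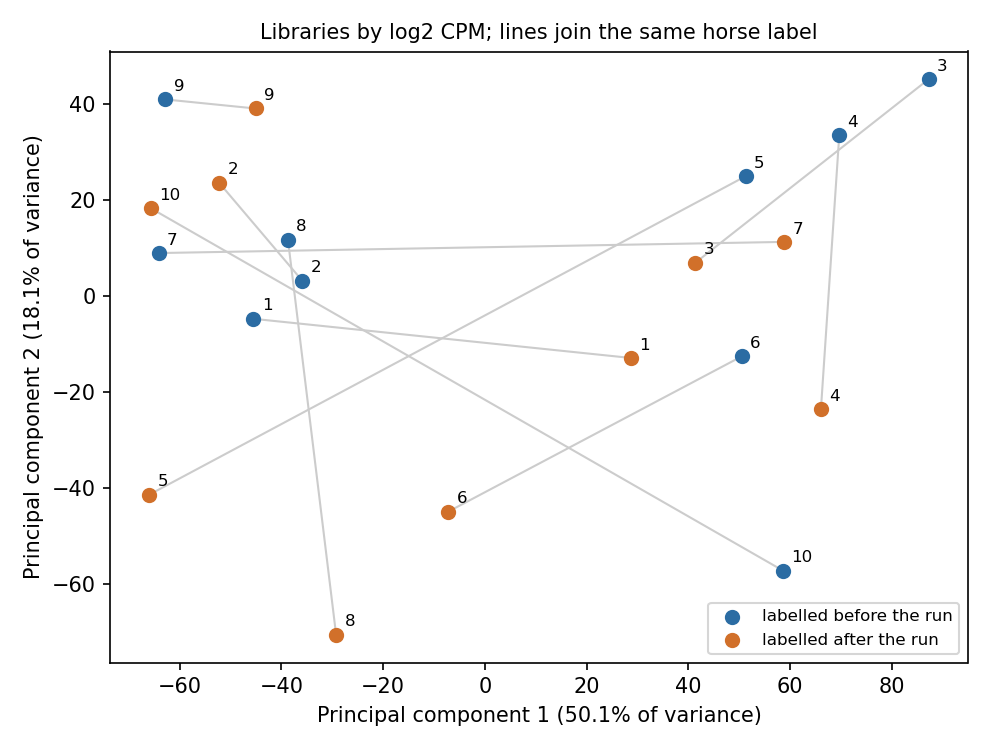
Scores of the 20 libraries on the first and second principal components of log2 CPM, with the percent of variance on each axis. Colour gives the run label, numbers give the horse label, and grey lines join libraries with the same horse label. Each run label has 5 libraries among the 10 highest scores of the first component.

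Across all genes, libraries with the same horse label were on average no more alike than libraries with different ones. After the mean of each run label was subtracted, the correlation across genes between the before and after library of a horse had a median of 0.171 and ranged from -0.717 to 0.652. It was positive in 6 horses and negative in 4, which were horses 1, 5, 7 and 10. Those 4 are the horses with 1 library among the 10 highest and 1 among the 10 lowest scores of the first component. The correlation therefore depends on position on that component. Libraries of 1 animal that part along it would also fail this check. Between different horses the median was -0.0194, with a range of -0.744 to 0.803. The mean was -0.00025 for the same horse and 7.77e-05 for different horses (permutation p = 0.502, one-sided, 100000 permutations of the horse labels, added after the data were seen). Each library was also compared with the 10 libraries of the other run label. In 2 of the 20 libraries the highest correlation was with the library of their own horse label, about as many as arbitrary horse labels would give. No library had been deposited more than once, since the lowest chi-square per degree of freedom among the 190 pairs of libraries was 35.8.

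The libraries were then compared, after the data had been seen, on genes that vary little along the main components. On a panel of the 100 most variable such genes, after removal of the first 2 components, the 20 libraries fell into 10 pairs with a mean correlation of 0.736 (range 0.432 to 0.888). The pairs were before 1 with after 4, before 2 with after 3, before 3 with after 2, and before 4 with after 9. Within the before label they were before 5 with before 9, before 6 with before 7, and before 8 with before 10. Within the after label they were after 1 with after 5, after 6 with after 8, and after 7 with after 10. In 9 of the 10 pairs, each library was the other's closest match. The exception was before 4 with after 9, at 0.432. Pairs with the same horse label had a mean correlation of -0.167 (range -0.368 to 0.0442), and 0 of the 10 matched pairs carried the same horse label. When each panel gene was shuffled over the libraries, the best matching reached a mean correlation of at most 0.195 in 100 draws. Shuffling each gene on its own also removes the correlation between genes. The draws therefore show that the libraries share structure on the panel, and not where it comes from. With 8 components removed, the best matching still had a mean correlation of 0.473, although it shared 1 pair with this matching.

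**Figure D3:**
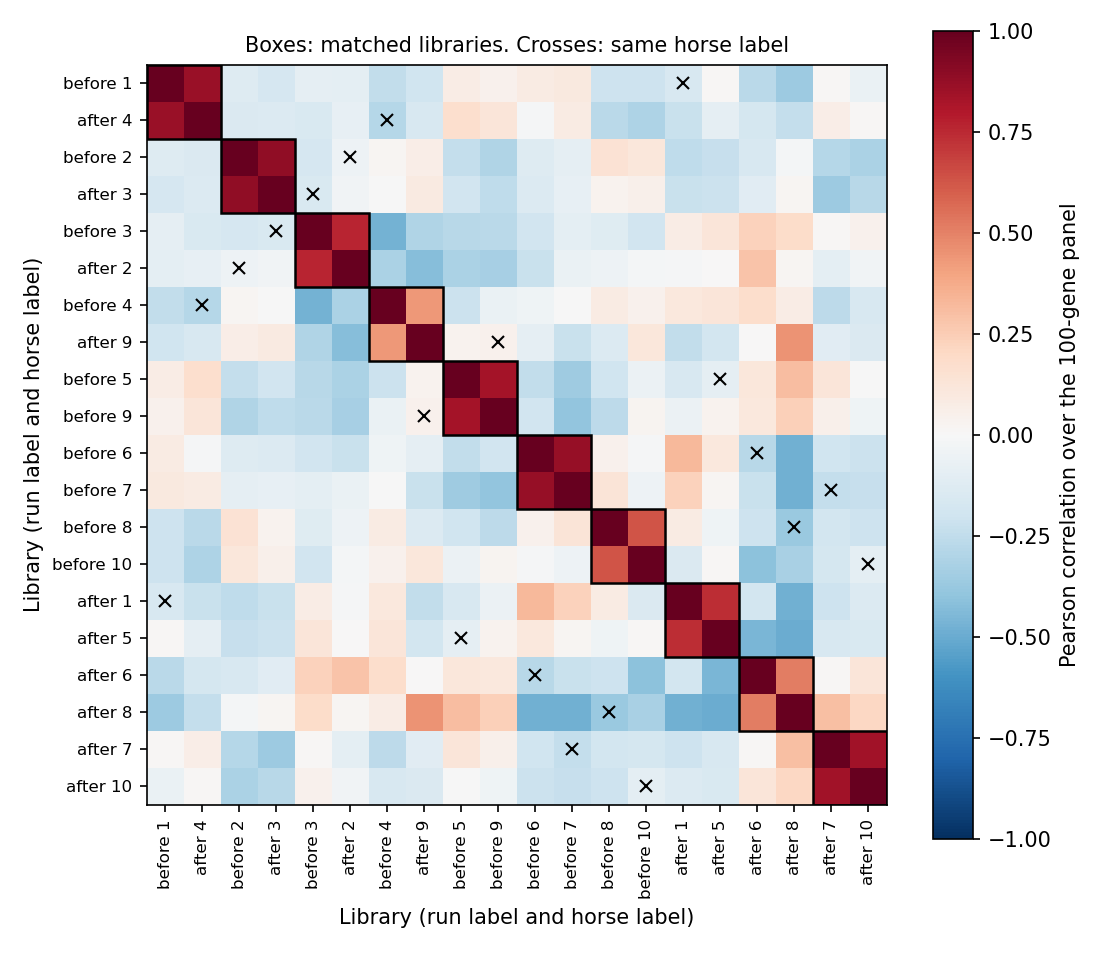
Pearson correlation of each pair of libraries over the 100-gene panel (colour scale from -1 to 1), with libraries named by run label and horse label. Boxes hold the 10 matched pairs, whose correlations range from 0.432 to 0.888, and crosses mark libraries with the same horse label, which range from -0.368 to 0.0442.

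The 5 genes left out of the panel had at most 4 reads in some libraries and at least 1 CPM in others. ENSECAG00000041907 had 8.68 to 13.2 CPM in 6 libraries (before 1, after 4, before 3, after 2, before 8 and before 10) and at most 0.205 CPM in the other 14. ENSECAG00000037364 had 1.63 to 5.00 CPM in 10 libraries and at most 0.142 CPM in the other 10. Libraries with the same horse label differed in presence in 24 of 50 comparisons, and 9 of these 10 pairs differed in at least 1 gene. Random matchings of the libraries had a median of 20 differences, and the horse labels had no fewer than chance (permutation p = 0.989, one-sided). This test asked for fewer differences only, and an excess was not tested. By gene in order of identifier, pairs with the same horse label differed 2, 6, 4, 6 and 6 times. The most possible is 2, 10, 4, 6 and 6, the number of libraries in the smaller of the present and near-0 groups. The matched pairs had 0 differences in 50, where the lowest of 100000 random matchings had 4 (permutation p = 1e-05, the smallest these draws can give). That p is not an independent test of the matched pairs, because these genes had been seen when the panel was chosen among several.

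Both results were recomputed with every panel and gene definition that was tried. In 11 panels with up to 4 components removed, 8 to 10 of the pairs were found again. With 6 components removed, 6 or 7 were found, and with 8 removed, 1. None of these panels paired libraries with the same horse label. Under 4 wider definitions of genes present or near 0, with 85, 39, 24 and 12 genes, the horse labels had no fewer differences than chance (permutation p = 0.246, 0.417, 0.509 and 0.514). The matched pairs had fewer differences than chance with 39, 24 and 12 genes (p = 0.0002, 0.0001 and 0.0218 in 10000 random matchings, 0.0001 being the smallest these can give) but not with 85 (p = 0.169). These p-values are not independent tests either, since the wider sets had also been seen when the panel was chosen and were not left out of it. Matchings made from these genes alone shared 2, 2, 6 and 2 pairs with the panel, and the one from 85 genes held 2 pairs with the same horse label.

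**Figure D4:**
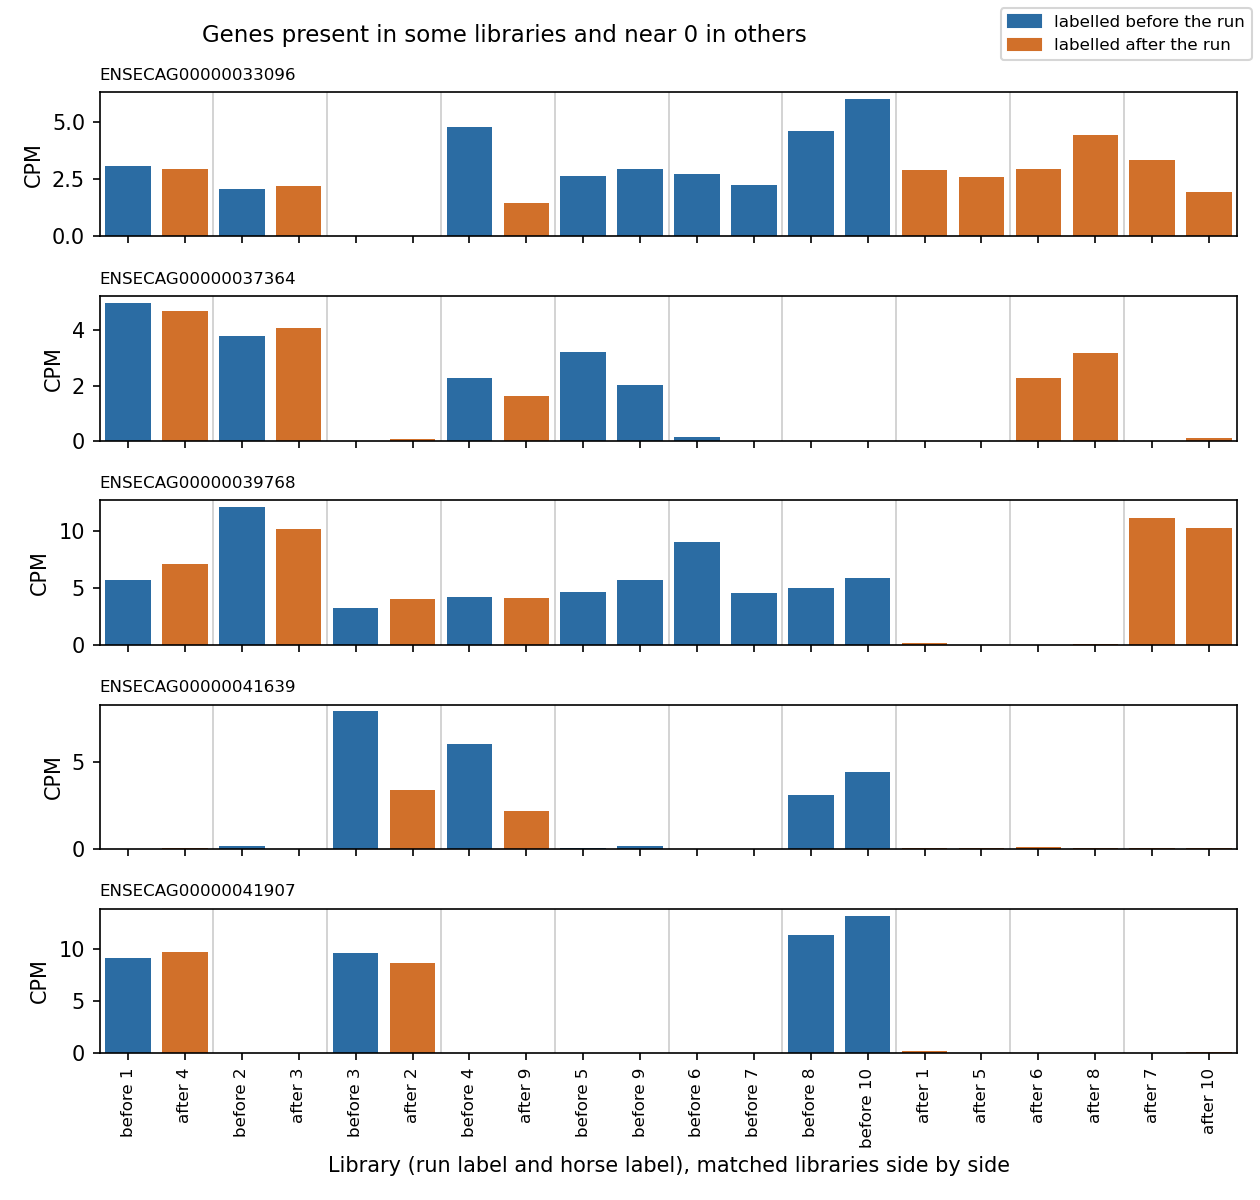
CPM of the 5 genes that are near 0 in some libraries, 1 panel per gene, with each panel's vertical axis starting at 0. Bars are single libraries, coloured by run label, and matched libraries stand side by side between grey lines. Both libraries of each matched pair are present or near 0 together in all 5 panels.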

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

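The outlier test in this part was not chosen after the results were seen. Its 28 groups of values included library measures that were not planned, among them the share of reads aligned to several places. They also included the CPM of the genes named for the run comparison, which were chosen after their values were seen. The library labelled after the run for horse 8 had 6.07% of its reads aligned to several places, where the next highest of the 10 after libraries had 3.13%. Its gap to the next library was 0.827 of the group's range, above Dixon's 95% critical value for 10 libraries. It was the only such library in 28 groups of values, where chance picks out about 1 in 20 groups. No technical or biological explanation was tested.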

How the results depend on the processing

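The covariate settings and the permutation test that ignores the horse label were chosen after the results were seen. The count of 0 genes past the adjusted threshold held for every alternative but DESeq2, which called 1 gene after the run, also 1 at 2-fold or more. The paired design entered as a replicate block; with no replicate block the count was 0 as well, with 581 genes at an unadjusted p under 0.05 against 391. The unadjusted count moved by more than 1.5 times when single horses were left out, between 177 and 1537. It was lower without horse 3, 4, 5, 6 or 8 and higher without horse 7 (1537) or 10 (1021). Beside the block, the added covariates moved it to 217 for total count and 841 for the share of reads outside genes. With the first 2 principal components and no replicate block it was 1312, to be set against the 581 without the block. Each had 0 genes past the adjusted threshold. Its majority direction, 240 higher and 151 lower, turned with total count (63 and 154) or reads outside genes (384 and 457) as a covariate and without horse 5 (95 and 104) or 10 (494 and 527). With RLE size factors it was 197 and 171. With adjustment over all 8 library measures, the differences in depth and in reads outside genes passed the exact sign-flip test at 0.05 only without horse 7 (adjusted p = 0.0156 for each). Over the horses left out these differences ranged from 3467310 to 4790090 counts and from -2.98 to -2.21 percentage points. The 4 named genes kept the sign of their fold change under all alternatives. The log2 fold change of ENSECAG00000043002 went from 2.91 to 3.68 with no block and to 2.32 with total count as a covariate, and that of ENSECAG00000031565 went from -0.78 to -0.31 with total count and to -0.43 with reads outside genes as a covariate. The cause of these changes was not tested. Gene list tests, list scores and the removal of haemoglobin genes were not run, since the files give no gene names. What can be seen is limited, since 51 of 100 genes given a 2-fold change were recovered. Whether depth or spread between libraries sets this limit was not tested.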

Other observations

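The tests below were chosen after the results were seen. For the corrections of the first principal component for total counts and for reads outside genes, the predictions were written before the corrections were run. They concern the matched pairs, so they too came after the matching.

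The first pattern is that edgeR called 0 genes between the run labels and DESeq2 called 1, while the libraries differed strongly from each other. A candidate explanation is that the horse and run labels do not follow the animals. Libraries with the same horse label differed in 24 of 50 comparisons of genes present or near 0, where random matchings had a median of 20. The matched pairs had 0, which is not independent evidence, because these genes had been seen when the panel was chosen among several. With 85 genes under a wider definition, the matched pairs had no fewer differences than chance (permutation p = 0.169). With 39, 24 and 12 genes they had fewer. If matched libraries came from 1 animal, 6 of the 10 pairs would carry the same run label on both libraries, which the design does not allow; relatives or shared handling were not tested. A spread between libraries too large to see 4-fold changes is argued against, since 89% of 100 such genes were recovered. This covers genes with a mean of at least 2 CPM and a change that is the same in all horses. That the run changed few transcripts cannot be told apart from this, since only 4 matched pairs hold 1 library of each run label, with the after library higher on the first component in 2 and lower in 2.

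The splits of the libraries cannot test the count of genes past the adjusted threshold, because it was 0 and every split gives at least as many. With the horse block, that was 50 of 50 splits that part every labelled pair, the highest other giving 0, and with no block 50 of 50, the highest other giving 1. For the count at an unadjusted p under 0.05, chance cannot be excluded: 22 of 50 splits gave at least the 391 genes of the real split with the block, and 20 of 50 at least the 581 without it. The other splits had medians of 267 and 337 genes and highest counts of 3135 and 4484. Single splits with several times the real count may point to a structure of the libraries, which was not tested.

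The second pattern is that each of the 10 matched pairs has 1 library among the 10 highest and 1 among the 10 lowest scores of the first component, against 4 of the labelled pairs; parted by the sign of the score, 9 matched and 5 labelled pairs lie on different sides, since after 6 (-7.14) and after 8 (-29.2) are both below 0. By rank, a fixed random matching does this with an exact probability of 0.00554, 1 of 100 matchings of shuffled panels did, and with 3 or 4 components removed from the panel of 100 genes 8 pairs did. Neither of the first 2 values is a chance level for this matching. The panel had the first component removed and held genes little related to it, which can itself favour pairs on opposite sides. Shuffling the panel undoes this. Sequencing depth stays open: thinning every library to 17280682 counts left 10 of 10 pairs parted by rank but moved the scores too little to be a test (correlation 0.999997), and with log2 total count regressed out of every gene 8 of 10 stayed parted by rank and 9 by sign, as many by sign as before (correlation of scores 0.947). The share of reads outside genes also stays open, but more of the pattern was lost with it than with total count. After it was regressed out, 6 of 10 pairs stayed parted by rank and 6 by sign (correlation of scores 0.808). This regression also removes any biological change that goes with the share. A change shared by every animal, such as the run, cannot be told apart here, because the run label accounts for 1.69% of the component and the labels are themselves in doubt.

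The third pattern is ENSECAG00000043002, the gene called by DESeq2, which had 0.536 to 5.93 CPM in the before libraries and 1.22 to 107.9 CPM in the after libraries. A candidate explanation is a difference between animals. This gene is outside the panel, and matched pairs accounted for 89.9% of its variance in log2(CPM + 0.5). Random matchings with as many pairs of each combination of run labels had a median of 52.0%, and the permutation p was 0.0037 in 100000 of them. The gene was chosen for its difference between run labels and the matching depends on the panel, so a change with the run stays open beside it.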
